A study of Mus musculus with 6 samples.

How the data were processed

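The series holds RNA sequencing of bone marrow derived macrophages from 3 samples of mice lacking the miR-130b/301b cluster (KO) and 3 samples of wild-type mice (WT). The authors deposited one table of 6 columns with values in CPM (counts scaled to the library total) per gene, per the file headers, with a gene identifier and a symbol for each gene. The submitters' processing notes name the genome build GRCm39. The aligner, counter, annotation, strand setting and scaling method were not given in the sources used here. The labels state paired-end sequencing of total RNA. The columns summed to between 989223 and 1018258 and the highest exceeds what division by library size alone can give, so the deposited CPM carry a scaling between libraries besides division by library size. The deposited file also holds a single unlabelled p-value beside the gene Cd5l, 0.0481, which equals a comparison of that row's KO and WT values in the authors' deposited table and was used in no test. No other column of sample values was left unused (0).

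The table lists 13254 genes; 333 have an identifier in place of a symbol. Depth in reads is unknown. Low values lay near multiples of a small step, but only between 26.4% and 60% of those under 0.4 CPM lay within 0.1 of a step of a whole multiple, depending on the sample, so whole reads were not recovered. No interval or detection floor was therefore computed, and 0 is reported as listed at 0. The 6 columns held no identical pair. Mitochondrial genes made up between 1.25% and 1.48% of each column.

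Samples were grouped by the genotype in their labels. Genes with at least 1 CPM in at least 3 samples were tested, 11556 in all. Values were transformed to log2(CPM + 1), and KO was compared with WT by a linear model with empirical Bayes moderation and a mean-variance trend (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg (BH) adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale and understate the change of low genes. Replicate numbers did not enter the model, since the labels give them no meaning beyond a name. Single genes at the targeted locus were also compared by an exact permutation test of the 20 labelings, whose smallest two-sided p is 0.1.

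Before the data were examined, 32 gene lists were fixed, covering efferocytosis, phagocytosis, lysosomes, lipid handling, activation states, metabolism, stress responses and markers of other cell types. Lists with at least 5 tested members, 28 in all, were compared with the other genes by camera with a preset correlation of 0.01, and again with an estimated correlation and by fry, each with BH adjustment over the lists. The text names the 10 largest increases and the 10 largest decreases past the test whose groups did not overlap, leaving out unnamed gene models and names ending in -ps (a rule that kept Eif3s6-ps2, annotated as a processed pseudogene), up to 4 members of each list past the test or its 2 most abundant members, 15 genes fixed in advance, the listed genes around the cluster and Y-linked genes. Some genes of this rule are not reported here. Genes with an identifier in place of a symbol counted as unnamed, a reading of the rule made after the data were examined. Genes outside this rule are said to have been chosen after their values were seen, as were the measures Lyz2 and Csf1r, given as levels.

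Gene positions and 3′ UTR sequences came from GENCODE M21 on GRCm38, which differs from the build in the submitters' processing notes. Coordinates are given only for the cluster, its host and Sdf2l1, and a distance only for Ciita. Gene order is otherwise used without coordinates. Of the 13254 identifiers, 12676 matched that annotation, and 11279 of the tested genes did. Seed matches were searched in the longest annotated 3′ UTR of each gene, present for 92.5% of the tested genes, and set against 299 control heptamers of the same base composition without CpG. Text handling used Python 3.11.15.

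The limma model was tested on simulated data for the 11556 genes of this comparison, in 5 simulations with known changes. It found 82.1% of genes changed by 0.5 on the log2 scale, 99.7% of those changed by 1 and 100% of those changed by 2, and 7.58% of its calls were false. Camera found the raised list in 5 of 5 simulations and called 0 other lists. The raised list moved by more than the median change of most lists that camera called in the real samples. Its recovery therefore does not show how small a shift camera can find. The simulated genes varied independently, whereas the estimated correlation within a list reached 0.794 in the real samples (stromal markers). The simulations therefore cannot show how often camera calls an unchanged list whose genes vary together.

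The alternatives tried were pseudocounts of 0.1, 0.5 and 5, no filter and a mean of at least 5 CPM, rescaling by median-of-ratios factors, quantile normalization, no trend, robust moderation, array weights, a replicate block, an adjusted p of 0.1, a 2-fold limit and leaving out each sample in turn. After the data were examined, fits without the genes in chromosomal runs, without the stromal list, and with the stromal level as a covariate were added.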

Results

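RNA sequencing measured gene expression in bone marrow derived macrophages (BMDMs, macrophages grown from marrow precursors in culture) of wild-type (WT) mice and of mice lacking the miR-130b/301b microRNA cluster (KO). There were 2 groups of 3 samples each, 6 in all. The series title ties the deletion to efferocytosis, the uptake of dead cells by macrophages, and to resolution of adipose tissue inflammation. The comparison of KO with WT asks which transcripts of these programmes differ in culture. The deposited values were CPM (counts scaled to the library total) for 13254 genes, and the columns summed to between 989223 and 1018258. Depth in reads was unknown, so no counting interval is given. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

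The samples of a genotype resembled each other more than those of the other genotype. Pearson's r across genes of log2(CPM + 1) lay between 0.9945 and 0.9962 within a genotype and between 0.9915 and 0.9933 across genotypes. The first principal component held 43.7% of the variance and separated KO from WT. The second held 18.7% and set KO replicate 2 apart. Macrophage genes were abundant in both groups: the lysozyme gene Lyz2 stood at 12163 ± 490 CPM in KO and 10513 ± 180 in WT, and the CSF1 receptor gene Csf1r at 2368 ± 86.6 and 2187 ± 149 (mean ± SD, n = 3 here and below). The Y-linked genes Ddx3y, Kdm5d and Uty were present in all 6 samples at similar levels, while Xist was not analysed here. A further Y-linked gene, Eif2s3y, stood at 25.9, 44.7 and 25.1 CPM in KO replicates 1, 2 and 3 and at 46.5, 47.9 and 50.4 CPM in the WT samples. Its difference did not pass the test with all samples (limma, Benjamini-Hochberg (BH) adjusted p = 0.207) and passed it without KO replicate 2 (log2 fold change -0.90, limma, BH-adjusted p = 0.000178).

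The transcript that hosts the deleted microRNAs was listed at 0 in every KO sample. Mir130b and Mir301b themselves were not analysed here. On GRCm38 (GENCODE M21), which differs from the GRCm39 build in the submitters' processing notes, Mir130b lies on chromosome 16 at 17124061 to 17124142 and Mir301b at 17124400 to 17124496. Both are on the minus strand in the first intron of the host gene 2610318N02Rik (17113398 to 17125167), between exon 1 (17124990 to 17125106) and exon 2 (17123512 to 17123654). The host was listed at 0 CPM in KO replicates 1, 2 and 3 and at 1.63, 2.43 and 2.07 CPM in WT replicates 1, 2 and 3. It was chosen after its values were seen. An exact two-sided permutation test gave p = 0.1, the smallest that 3 samples against 3 allow, and limma gave a BH-adjusted p of 0.000804.

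Of the neighbouring protein-coding genes reported here, Sdf2l1 fell and the others did not pass the test. Sdf2l1, which encodes an endoplasmic reticulum protein and lies on the same strand at 17130138 to 17132383, stood at 57.0 ± 1.92 CPM in KO and 77.6 ± 0.988 in WT (log2 fold change -0.44, limma, BH-adjusted p = 0.00106; exact permutation p = 0.1). Ppil2 (log2 fold change 0.07, limma, BH-adjusted p = 0.635), Ube2l3 (-0.09, adjusted p = 0.249), and Top3b (-0.18, adjusted p = 0.376) did not pass it, nor did Ydjc and Hic2. Ypel1 and Tmem191 lay under the filter on low values.

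**Figure D1:**
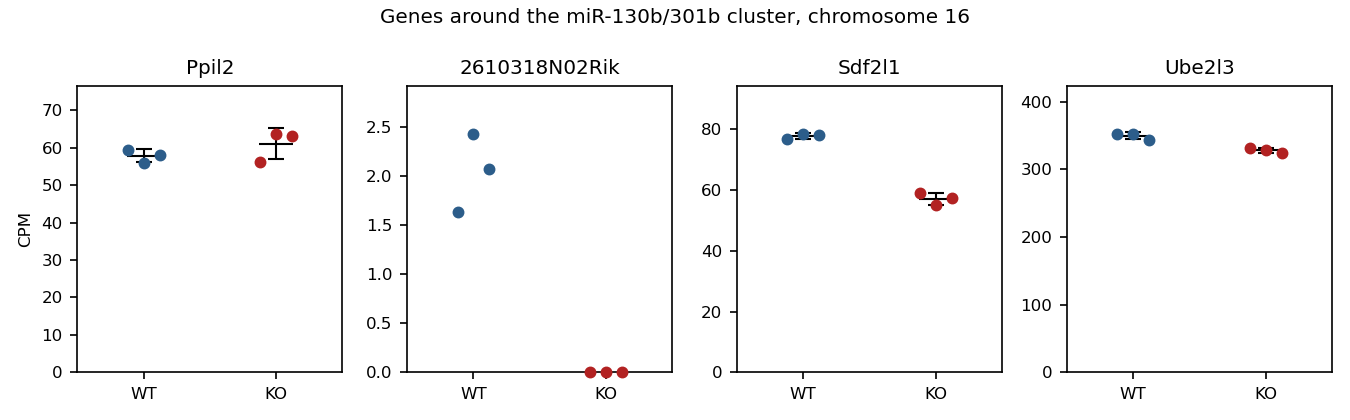
CPM per sample of 4 genes around the miR-130b/301b cluster, with the mean and SD of 3 samples as black bars (points alone where a sample is listed at 0). 2610318N02Rik, the host of the cluster, is at 0 in all KO samples; Sdf2l1 is lower in every KO sample than in any WT sample.

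Across the transcriptome, 147 of 11556 tested genes differed between KO and WT, with 56 higher and 91 lower in KO (limma on log2(CPM + 1), BH-adjusted p under 0.05). Changes of at least 2-fold were 17 increases and 16 decreases. In KO, Il1r1, the signalling receptor of interleukin-1, rose from 0.610 ± 0.140 to 6.61 ± 0.152 CPM. Angpt1, the ligand of the Tie2 receptor, rose from 1.19 ± 0.313 to 10.2 ± 1.51 CPM. The adhesion molecule gene Cadm1 rose from 193 ± 8.19 to 508 ± 18.3 CPM and Tmem64 from 13.6 ± 0.253 to 51.6 ± 1.67 CPM. Ctnnd2, which encodes delta-catenin, fell from 16 ± 1.69 to 1.97 ± 0.508 CPM. Creg2 fell from 17.4 ± 1.56 to 3.95 ± 0.571 CPM, and Lrp12 from 157 ± 3.93 to 72.9 ± 0.998 CPM.

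On the log2(CPM + 1) scale, which understates the change of low genes, the largest increases of genes with a name were Angpt1 (2.35, SE 0.142, limma, BH-adjusted p = 6.73e-05), the phospholipid flippase gene Atp10d (2.34, SE 0.167, adjusted p = 0.000212), Il1r1 (2.24, SE 0.106, adjusted p = 1.32e-05), the presynaptic scaffold gene Rims2 (2.16, SE 0.0872, adjusted p = 5.14e-06). They were followed by the adhesion molecule gene Clmp (2.15, SE 0.0937, adjusted p = 8.7e-06), Tmem64 (1.85, SE 0.0491, adjusted p = 5.26e-07), the dihydropyrimidinase gene Dpys (1.52, SE 0.167, adjusted p = 0.00328) and Cadm1 (1.40, SE 0.0424, adjusted p = 8.36e-07). Also among the 10 largest were Rnf26rt, listed at 0 in the 3 WT samples, and Eif3s6-ps2, which rose by 1.75. Both names mark copies of other genes, and reads shared with the parent gene make their values uncertain. GENCODE M21 types Atp10d as a polymorphic pseudogene and not as a protein-coding gene. The largest decreases were Ctnnd2 (-2.53, SE 0.138, limma, BH-adjusted p = 3.53e-05), the type III collagen gene Col3a1 (-1.92, SE 0.264, adjusted p = 0.0133), Creg2 (-1.90, SE 0.106, adjusted p = 3.64e-05), Zfp951 (-1.28, SE 0.171, adjusted p = 0.0117), Junos (-1.23, SE 0.118, adjusted p = 0.00136). Smaller decreases were those of the collagen gene Col12a1 (-1.16, SE 0.216, adjusted p = 0.0456), Cd200, whose product is the ligand of an inhibitory receptor on myeloid cells (-1.14, SE 0.217, adjusted p = 0.0498), AU022793 (-1.13, SE 0.108, adjusted p = 0.00136), the matrix protein gene Postn (-1.12, SE 0.211, adjusted p = 0.0482) and Lrp12 (-1.10, SE 0.0351, adjusted p = 1.01e-06). Junos lies opposite Jun, which also fell (-0.33, limma, BH-adjusted p = 0.00136), and without strand information their reads cannot be told apart. Zfp951 lost the call without KO replicate 1 (adjusted p = 0.0584) and WT replicate 3 (adjusted p = 0.0646). Col12a1 kept it only without KO replicate 3 and Cd200 only without WT replicate 1, with limma, BH-adjusted p up to 0.173 (Col12a1, without KO replicate 1) and 0.202 (Cd200, without WT replicate 2).

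The number of genes past the test depended on single libraries: it was 63 without KO replicate 1, 58 without WT replicate 2, 55 without WT replicate 3 and 243 without WT replicate 1. The KO and WT samples of all 147 genes did not overlap, as held for 17.7% of the tested genes, where chance gives 10%. A further 13 of the 147 were gene models without a proper name (8 higher, 5 lower), among them the pseudogene models Gm12191, at 61.2 ± 5.18 CPM in KO and 0.221 ± 0.383 in WT, and Gm15459, at 392 ± 6.83 and 12.1 ± 0.935, both chosen after their values were seen.

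The genes past the test lay close together on the chromosomes, a count made only after the data were examined. Of the 143 with a position in GENCODE M21, 76 (53.1%) had another within 10 tested genes, while 10000 random draws of as many tested genes gave a median of 31 and at most 55. Runs of at least 3 such genes numbered 10, on 7 chromosomes, and held 56 of the 143 genes, 22 higher and 34 lower in KO. Chromosome 15 held 24 among its 425 tested genes (Fisher's exact test, two-sided, with BH over all chromosomes, adjusted p = 1.38e-08). Its run of 20, from Basp1 to Emc2, held Ctnnd2, Rims2, Dpys, Lrp12 and Angpt1. A run on chromosome 1 held Creg2, Il1r1 and Col3a1, and runs on chromosomes 4, 5 and 9 held Tmem64, Atp10d and Clmp. Other runs, of 3 genes each, held Jun and Junos on chromosome 4 and Mmp8 and Mmp12 on chromosome 9.

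**Figure D2:**
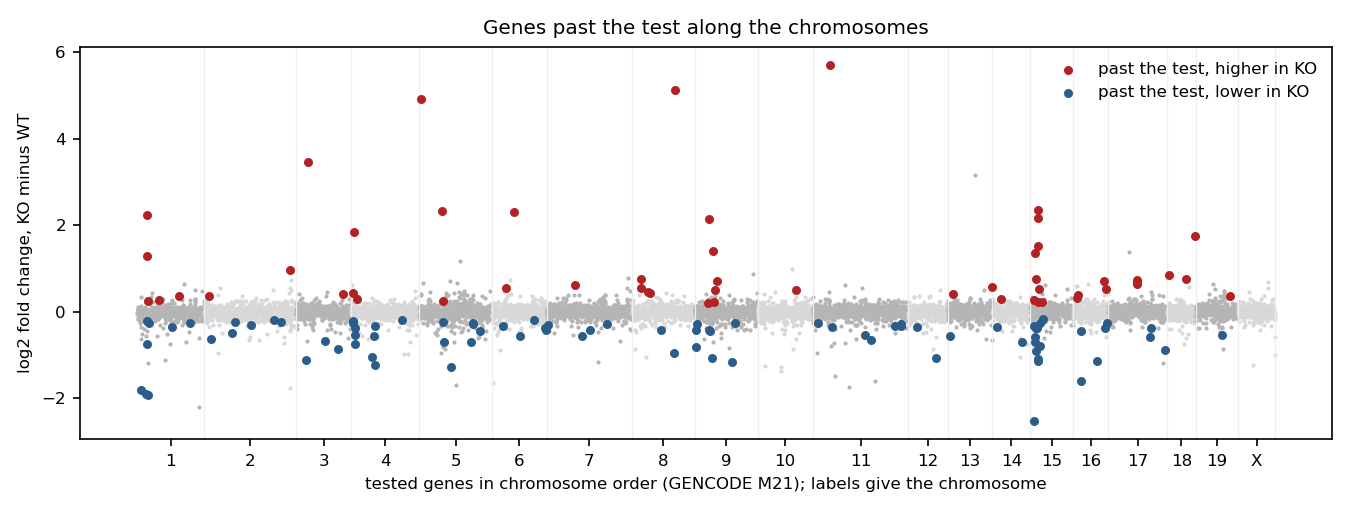
Log2 fold change (KO minus WT, of log2(CPM + 1)) of the tested genes in chromosome order on chromosomes 1 to 19 and X; grey points did not pass the test, red and blue points passed it and were higher or lower in KO. The group on chromosome 15 includes Ctnnd2 at -2.53 and Angpt1 at 2.35.

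Most genes of efferocytosis did not pass the test between KO and WT, and the 2 that did were lower in KO. Of 30 tested receptors and bridging proteins, 2 fell and 28 did not pass the test. By limma 13 of the 30 had an unadjusted p under 0.05, 3 higher and 10 lower, as did 1449 of all 11556 tested genes in either direction. Adjusted over the list alone, 3 were higher and 3 lower. The 3 that were higher, Cx3cr1, Scarb1 and Pros1, were chosen after their values were seen. The largest change of the list was that of Cx3cr1, from 18.1 ± 6.40 to 33.1 ± 1.32 CPM (log2 fold change 0.88, limma, BH-adjusted p = 0.0739 over all genes, and 0.0121 adjusted over the list alone), which passed over all genes without WT replicate 1 (1.14, adjusted p = 0.000124). Mfge8, a bridging protein that links phosphatidylserine on dead cells to integrins, fell from 155 ± 9.73 to 117 ± 9.10 CPM (log2 fold change -0.41, SE 0.0637, limma, BH-adjusted p = 0.0219), and thrombospondin 1, Thbs1, from 795 ± 33.0 to 648 ± 35.1 CPM (-0.29, SE 0.048, adjusted p = 0.0266). The receptor gene Mertk stood at 67.3 ± 3.42 CPM in KO and 70.1 ± 3.66 in WT (-0.06, adjusted p = 0.715), and Axl at 104 ± 5.69 and 92.2 ± 15.8 (0.19, adjusted p = 0.501). Their ligand gene Gas6 stood at 282 ± 5.25 and 282 ± 7.09 (limma, BH-adjusted p = 0.996), the integrin gene Itgav at 139 ± 2.26 and 144 ± 4.86 (-0.05, adjusted p = 0.617), and the scavenger receptor gene Cd36 at 3112 ± 226 and 3417 ± 451 (-0.13, adjusted p = 0.637).

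The efferocytosis list as a whole was shifted down against the other genes (median log2 fold change -0.05; camera, BH-adjusted p = 0.0373 with a preset correlation of 0.01, and adjusted p = 0.397 with an estimated correlation). The estimated correlation of this list was -0.0289, below the preset 0.01, so the higher p does not come from members that vary together. Fry, which asks whether the list moved on balance one way, gave a BH-adjusted p of 0.015. The camera call was lost without KO replicate 3 (BH-adjusted p = 0.0545), WT replicate 1 (0.0557) and WT replicate 3 (0.0582). The calls of Mfge8 and Thbs1 changed with single libraries. The limma, BH-adjusted p of Mfge8 was 0.106 without KO replicate 1, 0.0613 without KO replicate 3, 0.0991 without WT replicate 2 and 0.0905 without WT replicate 3. That of Thbs1 was 0.0879, 0.1 and 0.0791 without KO replicate 1, WT replicate 2 and WT replicate 3. Axl passed it without WT replicate 1 (0.32, adjusted p = 0.0476). Engulfment machinery (camera, BH-adjusted p = 0.859) and LC3-associated phagocytosis and autophagy (adjusted p = 0.194) did not stand apart as lists, and 0 of the 30 genes in each passed limma's test (2 and 1 had an unadjusted p under 0.05). Actr3 and Cdc42, and Cybb and Rab7, were their most abundant members, with log2 fold changes between -0.07 and 0.05.

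**Figure D3:**
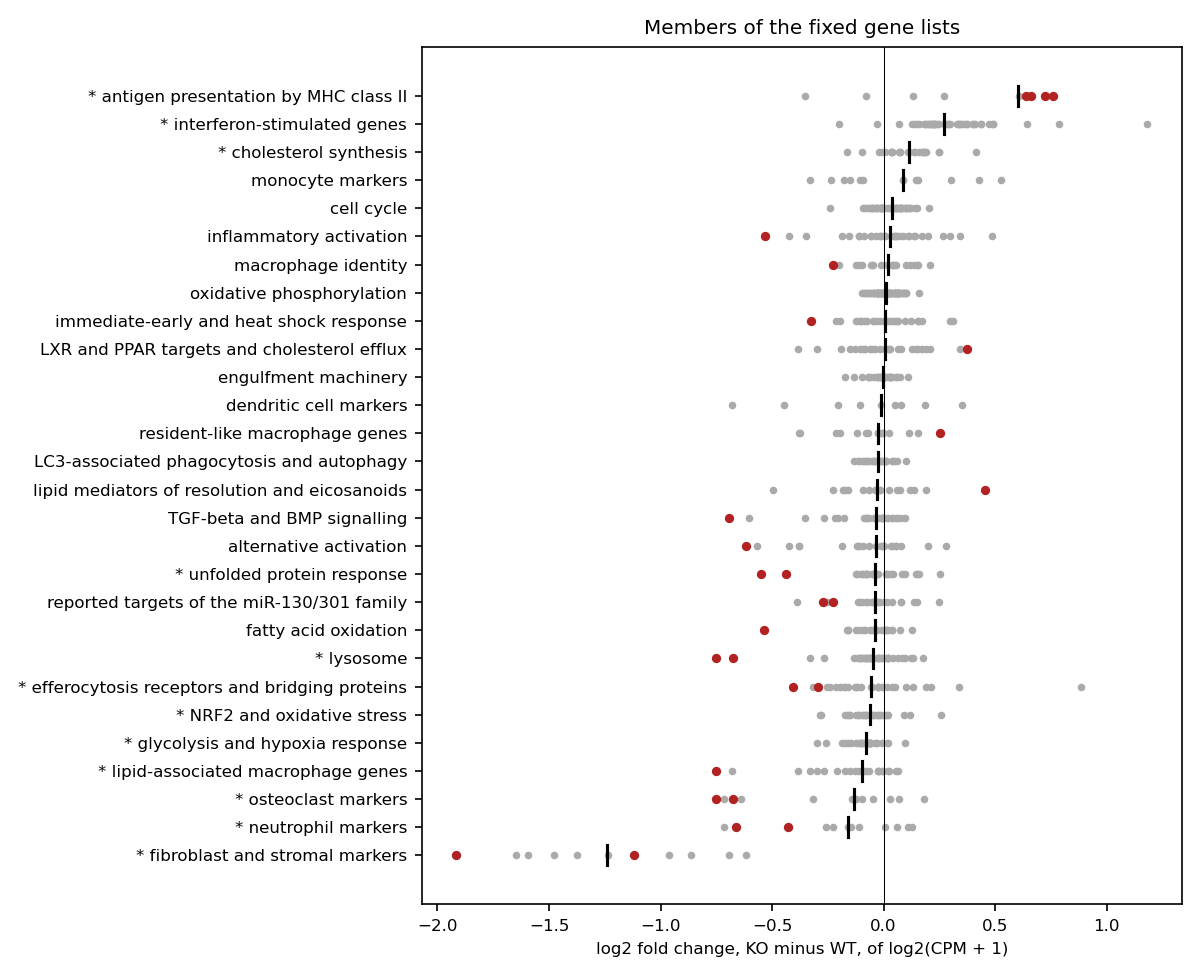
Log2 fold change (KO minus WT, of log2(CPM + 1)) of each member of the 28 gene lists tested; red points passed the test over all genes, black bars are list medians, and an asterisk marks a BH-adjusted camera p under 0.05 with the preset correlation. Stromal markers lie lowest (median -1.24), MHC class II highest (median 0.61).

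Genes of antigen presentation by MHC class II lay mostly higher in KO, with a positive fold change for 7 of the 9 tested. Of 9 tested, 4 rose and 5 did not pass the test; adjusted over the list alone, 6 were higher and 1 lower. The invariant chain gene Cd74 rose from 151 ± 18.9 to 256 ± 27.7 CPM (log2 fold change 0.76, SE 0.0991, limma, BH-adjusted p = 0.00952), H2-Ab1 from 22 ± 3.24 to 37.0 ± 4.57 (0.73, adjusted p = 0.0224), H2-Eb1 from 20.3 ± 3.28 to 32.5 ± 4.01 (0.66, adjusted p = 0.0456) and H2-Aa from 32.3 ± 3.74 to 50.9 ± 5.77 (0.64, adjusted p = 0.0219). Ciita, their master transcriptional activator, stood at 7.82 ± 1.24 CPM in KO and 4.79 ± 0.713 in WT (0.61, limma, BH-adjusted p = 0.0743). The lysosomal thiol reductase gene Ifi30 stood at 103 ± 6.71 and 132 ± 13.8 (-0.35, adjusted p = 0.0882). Ciita and Ifi30 were chosen after their values were seen. H2-Ab1, H2-Aa and H2-Eb1 are themselves a run of 3 adjacent tested genes on chromosome 17. The list stood apart from other genes with the preset correlation (camera, BH-adjusted p = 3.06e-05, 0.0404 without the genes in the spans of the runs, an alternative added after seeing the data), but not with an estimated correlation (adjusted p = 0.397). It was not called by fry (BH-adjusted p = 0.118). Without KO replicate 1 the limma, BH-adjusted p was 0.0575 for Cd74, 0.106 for H2-Ab1, 0.177 for H2-Eb1 and 0.106 for H2-Aa, and without WT replicate 2 it was 0.0549, 0.106, 0.161 and 0.1. H2-Ab1, H2-Eb1 and H2-Aa were also lost without KO replicate 3 (adjusted p = 0.0793, 0.137 and 0.0746), and H2-Eb1 without WT replicate 1 (adjusted p = 0.0611).

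Interferon-stimulated genes lay slightly higher in KO as a list, in large part through WT replicate 2, while none passed the test alone. Of 46 tested, 44 had a positive fold change, with a median of 0.27 (camera, BH-adjusted p = 7.08e-13, and adjusted p = 0.577 with an estimated correlation). By limma 0 passed the test, over all genes or adjusted over the list alone, and 18 had an unadjusted p under 0.05, all of them higher. Fry did not call the list (BH-adjusted p = 0.284). The most abundant members, Ifitm3 (571 ± 49.5 CPM in KO and 482 ± 44.6 in WT, limma, BH-adjusted p = 0.238) and Parp14 (278 ± 15.6 and 241 ± 32.9, adjusted p = 0.389), did not pass it. Ifnar1, a chain of the type I interferon receptor that was chosen after its values were seen, rose from 188 ± 6.32 to 311 ± 5.29 CPM (log2 fold change 0.72, SE 0.0356, limma, BH-adjusted p = 1.72e-05) and lies in a run of 4 genes past the test on chromosome 16. The mean log2 level of the interferon-stimulated list was 4.72, 4.91 and 4.66 in KO replicates 1, 2 and 3 and 4.65, 4.16 and 4.57 in WT replicates 1, 2 and 3. The mean log2 fold change of the list was 0.305 with all samples and 0.155 without WT replicate 2 (camera, BH-adjusted p = 1.34e-07).

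Genes of lysosomes, osteoclasts and lipid-associated macrophages shared their strongest change, a fall of Atp6v0d2. This subunit of the proton pump of lysosomes and osteoclasts fell from 578 ± 102 to 339 ± 8.08 CPM (log2 fold change -0.75, SE 0.111, limma, BH-adjusted p = 0.0173), and the protease gene cathepsin K, Ctsk, from 12.3 ± 1.45 to 7.32 ± 0.762 CPM (-0.67, SE 0.103, adjusted p = 0.0211). Atp6v0d2 lies in the run on chromosome 4 that holds Tmem64. Atp6v0d2 and Ctsk were the 2 of 42 lysosomal genes and the 2 of 12 osteoclast markers that fell; none rose. Adjusted over the list alone, 3 lysosomal genes were lower and 1 higher, and 5 osteoclast markers and 7 of 24 lipid-associated macrophage genes were lower. Lysosomal genes had a median log2 fold change of -0.05 (camera, BH-adjusted p = 0.00562, and adjusted p = 0.654 with an estimated correlation), osteoclast markers of -0.13 (adjusted p = 0.000574, and adjusted p = 0.577 with an estimated correlation) and lipid-associated macrophage genes of -0.10 (adjusted p = 3.2e-05, and adjusted p = 0.577 with an estimated correlation). Ctsb and Psap, the most abundant lipid-associated genes, did not pass the test (limma, BH-adjusted p = 0.877 and 0.534). The camera call of the lysosomal list was lost without WT replicate 3 (BH-adjusted p = 0.128). Atp6v0d2 and Ctsk lost the call without KO replicate 1 (limma, BH-adjusted p = 0.0879 and 0.0585), KO replicate 3 (0.0537 and 0.0538), WT replicate 2 (0.0879 and 0.0976) and WT replicate 3 (0.0623 and 0.0818).

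Few genes of lipid handling passed the test. Of 27 targets of the nuclear receptors LXR and PPAR and genes of cholesterol efflux, the desaturase gene Scd2 rose from 196 ± 10.1 to 256 ± 26.4 CPM (log2 fold change 0.38, limma, BH-adjusted p = 0.0476; p between 0.0533 and 0.201 without KO replicates 1 and 3 and WT replicates 1, 2 and 3, each left out in turn). The cholesterol exporter gene Abca1 (595 ± 59.4 and 611 ± 22 CPM, adjusted p = 0.86), Pparg (61.9 ± 1.52 and 58.6 ± 2.77 CPM, adjusted p = 0.529) and Apoe (4791 ± 340 and 4706 ± 234 CPM, adjusted p = 0.909) did not pass the test. The list did not stand apart (camera, BH-adjusted p = 0.693). Genes of cholesterol synthesis and uptake lay higher as a list (median 0.11, 0 of 24 past limma's test and 2 with an unadjusted p under 0.05, camera, BH-adjusted p = 0.0143, and adjusted p = 0.752 with an estimated correlation). Srebf2 stood at 127 ± 9.07 CPM in KO and 114 ± 6.92 in WT. That call was lost without KO replicate 2 (mean log2 fold change -0.0044, camera, BH-adjusted p = 0.888) and without WT replicate 3 (0.07, adjusted p = 0.134), and the mean rose from 0.105 to 0.178 without KO replicate 3. Fatty acid oxidation did not stand apart (adjusted p = 0.068), although its member Decr1, in the same run on chromosome 4 as Tmem64, fell (log2 fold change -0.54, limma, BH-adjusted p = 0.00248). Of the lipid mediator genes the prostaglandin-degrading enzyme gene Hpgd rose (0.46, limma, BH-adjusted p = 0.0324; camera, BH-adjusted p = 0.685 for that list). Hpgd kept its call only without WT replicate 1, and its highest BH-adjusted p was 0.143, without WT replicate 3.

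Genes of inflammatory and alternative activation mostly did not pass the test. Of 32 inflammatory genes 1 fell, the chemokine gene Ccl7 (26.2 ± 3.80 to 17.7 ± 0.552 CPM, log2 fold change -0.53, limma, BH-adjusted p = 0.0442). Tnf stood at 14.3 ± 1.55 CPM in KO and 12.9 ± 0.936 in WT (adjusted p = 0.571) and Il1b at 1.52 ± 0.280 and 1.60 ± 0.502 (adjusted p = 0.956). Of 23 genes of alternative activation 1 fell, the interleukin-1 receptor antagonist gene Il1rn (141 ± 20.2 to 90.9 ± 1.72 CPM, log2 fold change -0.62, limma, BH-adjusted p = 0.0173). The mannose receptor gene Mrc1 (802 ± 82.0 and 868 ± 31.0 CPM, adjusted p = 0.527) and the arginase gene Arg1 (1.15 ± 0.212 and 1.80 ± 0.444 CPM, adjusted p = 0.353) did not pass the test. Il10 lay under the filter. Neither list stood apart (camera, BH-adjusted p = 0.63 and 0.174). Ccl7 kept its call in only 1 of the fits that left out a library, that without WT replicate 1, and its highest BH-adjusted p was 0.194, without WT replicate 3. Il1rn lost it without KO replicate 1 (limma, BH-adjusted p = 0.0879), KO replicate 3 (0.0613), WT replicate 2 (0.0865) and WT replicate 3 (0.0755).

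Several metabolic and stress lists were shifted down by small amounts. Glycolysis and hypoxia genes had a median log2 fold change of -0.08 with 0 of 30 past limma's test and 8 with an unadjusted p under 0.05, all lower (camera, BH-adjusted p = 5.74e-06, and adjusted p = 0.577 with an estimated correlation). Their most abundant members Gapdh and Pkm did not pass it (limma, BH-adjusted p = 0.786 and 0.575). NRF2 and oxidative stress genes had a median of -0.06 with 0 of 29 past limma's test, 11 with an unadjusted p under 0.05 and, adjusted over the list alone, 5 lower and 1 higher (camera, BH-adjusted p = 0.000783, and adjusted p = 0.397 with an estimated correlation). Of 32 genes of the unfolded protein response 2 fell, the phosphatase subunit gene Ppp1r15a (log2 fold change -0.55, limma, BH-adjusted p = 0.0143) and Sdf2l1. The list had a median of -0.04 (camera, BH-adjusted p = 0.0424, and adjusted p = 0.577 with an estimated correlation). Ppp1r15a lost the call without KO replicate 1 (adjusted p = 0.0728) and WT replicate 3 (adjusted p = 0.0755). The list lost its call without KO replicate 2 (camera, BH-adjusted p = 0.0721), KO replicate 3 (0.0839), WT replicate 2 (0.183) and WT replicate 3 (0.0608). Oxidative phosphorylation (camera, BH-adjusted p = 0.232), the cell cycle (adjusted p = 0.107), TGF-beta and BMP signalling (adjusted p = 0.0693) and the immediate-early and heat shock response (adjusted p = 0.655) did not stand apart. Of the 28 lists tested, camera called 12 with the preset correlation and 0 with an estimated one (1 had an unadjusted p under 0.05), and fry called 1, that of efferocytosis.

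Transcripts of stromal cells were lower in KO, at low levels in both groups. Each of the 11 tested fibroblast and stromal markers had a negative fold change, 2 passed limma's test over all genes and 9 did not, and the median was -1.24 (camera, BH-adjusted p = 2.4e-10, and adjusted p = 0.434 with an estimated correlation). Col3a1 fell from 6.09 ± 2.24 to 0.881 ± 0.580 CPM and Postn from 2.30 ± 0.110 to 0.577 ± 0.536 CPM, and adjusted over the list alone all 11 were lower. Without KO replicate 1 the limma, BH-adjusted p was 0.0716 for Col3a1 and 0.17 for Postn, and without WT replicate 2 it was 0.0549 and 0.179. Postn was also lost without KO replicate 2 (0.103), WT replicate 1 (0.0783) and WT replicate 3 (0.198). The mean log2 level of the list was 1.67, 0.818 and 2.24 in KO replicates 1, 2 and 3 and 2.88, 2.73 and 2.79 in WT replicates 1, 2 and 3. With this level as a covariate, an alternative added after seeing the data, camera lost 4 calls besides that of the stromal list itself. The mean log2 fold change was -0.0373 without and -0.0377 with the covariate for efferocytosis (BH-adjusted p = 0.141 with it), and -0.0378 and -0.0534 for the unfolded protein response (0.109). It was 0.305 and 0.125 for the interferon list (0.14), and -0.0871 and -0.0617 for glycolysis (0.0876). The calls of MHC class II (3.82e-05), lipid-associated macrophages (3.82e-05), lysosomes (0.00488), neutrophils (0.00582), osteoclasts (0.00915) and NRF2 (0.0129) remained. The cell cycle list gained a call, up (2.93e-12), and cholesterol synthesis reversed (2.67e-05). Every KO level of the covariate lies below every WT level, so a lost or gained call does not tell a stromal source from the genotype.

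Of the markers of other blood cells, those of neutrophils fell as a list. Of 13 neutrophil markers 2 fell, the myeloperoxidase gene Mpo (6.88 ± 0.594 to 3.99 ± 0.482 CPM, log2 fold change -0.66, limma, BH-adjusted p = 0.0219) and the collagenase gene Mmp8 (10.3 ± 0.169 to 7.42 ± 0.543 CPM, -0.43, adjusted p = 0.0364). Adjusted over the list alone 4 were lower (camera, BH-adjusted p = 0.00349, and adjusted p = 0.397 with an estimated correlation). Mpo lost the call without KO replicate 3 (adjusted p = 0.0616), WT replicate 2 (adjusted p = 0.106) and WT replicate 3 (adjusted p = 0.0891). Mmp8 kept it only without KO replicate 3 (highest adjusted p = 0.159, without WT replicate 3), and the list lost its camera call without KO replicate 3 (BH-adjusted p = 0.0502). Mmp8 lies in a run of 3 genes past the test on chromosome 9, with Mmp12 and Maml2. Macrophage identity (camera, BH-adjusted p = 0.662), resident-like macrophage (adjusted p = 0.512), monocyte (adjusted p = 0.377) and dendritic cell markers (adjusted p = 0.859) did not stand apart. Itgax of the dendritic cell list stood at 146 ± 10.2 CPM in KO and 239 ± 57.8 in WT (-0.68, limma, BH-adjusted p = 0.106) and passed the test without WT replicate 1 (-0.89, adjusted p = 0.000694). Ccr2 of the monocyte list stood at 228 ± 18.2 CPM in KO and 172 ± 38.9 in WT (0.43, limma, BH-adjusted p = 0.245) and also passed it without WT replicate 1 (0.60, adjusted p = 0.0179). The iron exporter gene Slc40a1 of the resident-like list rose (log2 fold change 0.25, limma, BH-adjusted p = 0.0219; 0.0732, 0.0865 and 0.118 without KO replicate 1, WT replicate 2 and WT replicate 3). It lies in the run on chromosome 1 that holds Il1r1 and Col3a1. Lymphocyte, erythroid, mast cell and endothelial or adipocyte markers had 4, 2, 2 and 3 members above the filter, too few for a list test. None of these genes passed limma's test over all genes (3, 1, 1 and 0 had an unadjusted p under 0.05).

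**Figure D4:**
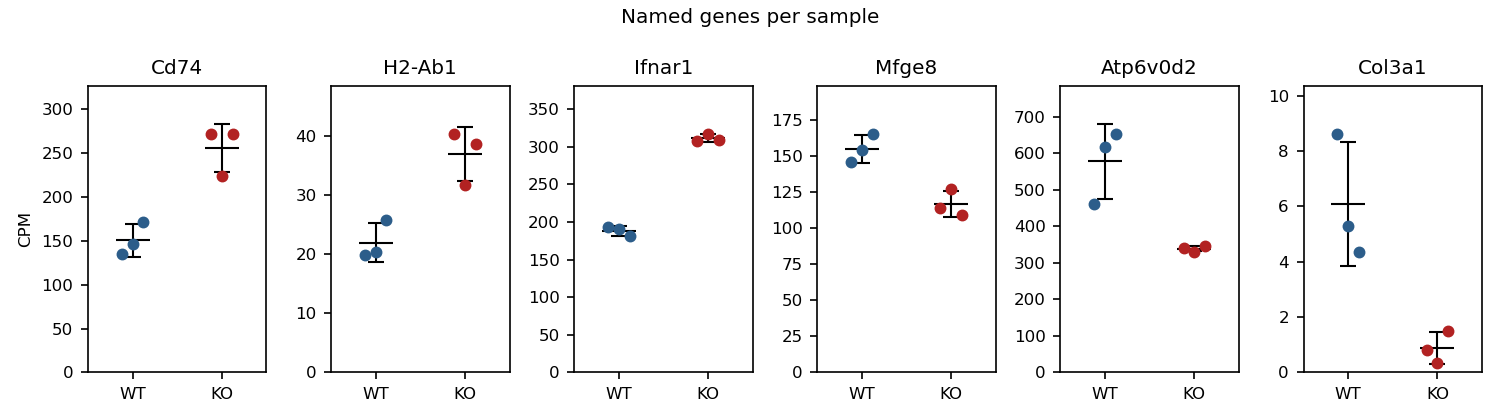
CPM per sample of 6 genes named in the text, with the mean and SD of 3 samples as black bars. Cd74, H2-Ab1 and Ifnar1 are higher in every KO sample than in any WT sample, and Mfge8, Atp6v0d2 and Col3a1 are lower.

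Genes with a predicted site for the deleted microRNAs did not lie higher in KO as a group. miR-130b-3p and miR-301b-3p share a seed, AGUGCAA, whose match in messenger RNA is TTGCACT. Of 10685 tested genes with an annotated 3′ UTR, 1275 held a match, and their median log2 fold change was -0.0124, against 0.00237 for genes without one. Camera, planned for this list alone, gave an unadjusted two-sided p of 0.171, direction down. Of 299 control heptamers of the same composition, 232 gave a difference at or above the -0.0148 of the seed match. Among genes with a match 2 rose and 17 fell, and among genes without one 46 rose and 67 fell (Fisher's exact test for increases, p = 0.117). Genes with a match had longer UTRs, with a median of 2469 bases against 1068.5. Of 25 tested genes reported as targets of the family, none rose and 2 fell, among them the protease inhibitor gene Timp2 (log2 fold change -0.27, limma, BH-adjusted p = 0.00653). The list did not stand apart (camera, BH-adjusted p = 0.174). Timp2 lost the call without WT replicate 3 (adjusted p = 0.0514).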

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

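The fits without the genes in chromosomal runs, without the stromal list and with the stromal level as a covariate were chosen after seeing the data; the others were fixed before the data were examined. All 147 genes past the test kept their sign in every alternative that tested them. For most alternatives this was fixed in advance, because the KO and WT samples of these genes did not overlap. Only rescaling, quantile normalization and the stromal covariate could have changed a sign. The count of 147 genes (56 higher, 91 lower) fell to 74 (36 lower) without the mean-variance trend and rose to 226 (143 lower) at an adjusted p of 0.1; at least a 2-fold change left 33 (17 higher, 16 lower) by construction. It was 52 (25 higher, 27 lower) without the 170 tested genes in the spans of the runs, and 52 (29 higher, 23 lower) with the stromal covariate, of which 29 were among the 147. Where not given by construction, the cause was not tested. Leaving out each sample in turn gave between 55 and 243 genes, with 29 to 80 higher and 23 to 163 lower: 63 without KO replicate 1, 58 without WT replicate 2, 55 without WT replicate 3 and 243 without WT replicate 1. Quantile normalization gave 144 genes with 43.1% higher, against 38.1%, and moved the median of all genes by less than 0.1. Camera called 12 lists, 0 with an estimated correlation, fry called 1, and leaving out each sample in turn gave between 8 and 14. Quantile normalization lost the camera calls of the efferocytosis (BH-adjusted p = 0.159), lysosome (0.239) and unfolded protein response lists (0.175), and no filter that of efferocytosis (0.052). With the stromal covariate the cholesterol synthesis list reversed to a mean of -0.205 (BH-adjusted p = 2.67e-05). Neighbours past the test were counted only with median-of-ratios rescaling, with the replicate block and without each sample in turn, and Sdf2l1 remained the 1 listed. The seed difference stayed between -0.0178 and -0.00572 when a sample was left out. Of 128 genes named or fixed in advance, 53 were past the test. Over 768 alternatives other than leaving out a sample, 725 kept their value or call. Of the rest, 21 calls were lost, 5 were gained, 17 values moved and 0 reversed. Over the 768 that left out a sample, 636 kept their value or call. Of the rest, 103 calls were lost, 10 were gained, 19 values moved and 0 reversed. Both tallies include genes not past the test, which had no call to lose. Same-numbered KO and WT samples deviated together by correlations of 0.00015, 0.083 and 0.065, under the limit of 0.1 set for treating the numbers as pairs; KO replicate 1 correlated best with WT replicate 3. With the replicate block, 142 genes passed the test, 111 of them among the 147. Of the 53 named genes past the test, 45 kept their call with the block and 8 lost it. The 2 planned count models were not run, because whole reads were not recovered. Depth is unknown, which limits what low values can show.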

Other observations

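The tests on chromosomal runs, on the Ciita neighbourhood, on dendritic cell markers and on the position of stromal genes were chosen only after the result was seen.

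Among genes outside the fixed lists, all chosen after their values were seen, the scavenger receptor gene Colec12 rose from 36.3 ± 0.539 to 66.5 ± 8.02 CPM in KO (log2 fold change 0.85, limma, BH-adjusted p = 0.00125). So did the lysosomal acetyltransferase gene Hgsnat from 142 ± 14.3 to 241 ± 12.5 CPM (0.76, adjusted p = 0.00125). The macrophage elastase gene Mmp12 fell from 1494 ± 362 to 829 ± 55.7 CPM (-0.82, limma, BH-adjusted p = 0.0482) and lost the call in every fit that left out a library except that without WT replicate 1, with p up to 0.196, without WT replicate 2. Single libraries lay more than 2-fold from both of their group mates, themselves close together, at few genes: 2 in KO replicate 1, 6 in KO replicate 2, 0 in KO replicate 3, and 1, 3 and 5 in WT replicates 1, 2 and 3. Among those of KO replicate 2, the pseudogene model Gm8730 was at 240, 12.8 and 223 CPM in KO replicates 1, 2 and 3 and at 1.86, 1.42 and 1.52 CPM in WT replicates 1, 2 and 3, and the kinase gene Grk3 at 7.75, 3.82 and 8.76 CPM in KO and 4.64, 3.37 and 3.21 CPM in WT.

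Genes past the test lay in runs along 7 chromosomes: 76 of 143 had another within 10 tested genes, against at most 55 in 10000 random draws. An effect of the deletion on its own surroundings is argued against as a source of the runs, since 7.14% of the genes in runs lie on chromosome 16, in a run without the host 2610318N02Rik and Sdf2l1, whose own falls remain compatible with a local effect. Reads shared with pseudogenes stay open. Pseudogenes made up 1.79% of the genes in runs (1 gene, Atp10d). They were 8 of the 143 genes past the test and 176 of the 11279 tested genes with a position. So low a share among all tested genes makes a low share in runs likely either way, and the count cannot see parent genes that share reads. Joint regulation of neighbours stays open: 50% of adjacent genes in runs moved the same way, against a median of 52.2% with shuffled directions (5% to 95% range, 39.1 to 63). A candidate explanation is that KO and WT mice differ in strain segments besides the deletion, a hypothesis that these values fit but that no sequence was used to test.

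Stromal markers were lower in KO, with the most abundant, Col1a2, at 8.50 ± 7.02 CPM in KO and 23.4 ± 1.47 in WT. A second list of stromal genes that shared none with the first, written before its values were seen, had a median log2 fold change of -0.63, with 23 of 25 tested genes lower. None of the 25 passed the test over all genes (lowest limma, BH-adjusted p = 0.0653, Col4a1). The mean log2 level of this second list was 1.43, 1.01 and 1.85 in KO replicates 1, 2 and 3. It was 2.13, 2.00 and 2.06 in WT replicates 1, 2 and 3. Macrophages also express some genes of the second list, such as Igfbp4, at 168 to 194 CPM in all 6 samples. The runs found here did not hold most of the markers. Of them 9.09% (1 of 11, Col3a1) lay in the span of a run, counting genes in a span whether or not they passed the test. Spans held only 170 of the 11279 tested genes with a position, so a low share was likely in advance. Segments without a run would also escape this count, so a strain segment as the source stays open. Fewer carried-over stromal cells in the KO cultures may account for the pattern, a hypothesis, and an effect of the genotype on stromal cells or on these transcripts was not tested.

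MHC class II genes lay mostly higher in KO, and 3 of the 4 past the test, H2-Ab1, H2-Aa and H2-Eb1, are themselves 1 of the 10 runs. Without the genes in the spans of the runs, the camera call of the list had a BH-adjusted p of 0.0404. With all genes the list was not called with an estimated correlation (camera, BH-adjusted p = 0.397) or by fry (BH-adjusted p = 0.118). The 7 tested dendritic cell markers on no other list did not rise as a set, with a median log2 fold change of -0.0115 (SE of the mean 0.0944). Single markers ranged from -0.448 (Fscn1) to 0.352 (Cd24a), and none passed the test. A small added share of dendritic cells need not move such a median, so it stays open. An interferon response cannot be told apart: with the interferon-stimulated level as a covariate the KO effect on the mean MHC class II level kept 116% of its value, with bounds from 42.5% to 189%. A strain segment around Ciita, the activator of these genes, is a hypothesis. Ciita lies on chromosome 16, as the deleted cluster does, 6.6 Mb from it on GRCm38. Of its 20 nearest tested genes 2 passed the test, Nubp1 and Snx29 (one-sided Fisher's exact test, p = 0.0261). That p treats genes past the test as scattered independently, whereas they lay in runs, so it may be too low. Nubp1 lost its call without every library but KO replicate 2 (limma, BH-adjusted p up to 0.124, without KO replicate 1). Ciita itself did not pass (0.0743). A strain segment at the MHC class II genes themselves and a direct effect of the microRNAs were not tested and stay open.

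Loss of repression through the shared seed was tested as a hypothesis and not borne out as a general shift: 232 of 299 control heptamers gave a difference at or above that of the seed match, and the median control difference was -0.0121. Mir130a and Mir301a, other genes of the family, were not analysed here, and whether they act on the same sites was not tested. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split was 1 of 10 for each result: it gave 147 genes past limma's test where the highest other gave 0 (1449 and 847 genes had an unadjusted p under 0.05), 12 gene lists where the highest other gave 10, and a seed difference of size 0.0148 where the highest other gave 0.014.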
